A study of Mus musculus with 16 samples.

How the data were processed

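Small RNA was measured in extracellular vesicles (EVs) from the bone marrow plasma of 16 mice that carried the CAGS-Snorkel reporter and 1 of 2 Cre drivers. Per the labels' protocols, EVs were captured on magnetic beads with an antibody to the HA tag, RNA was extracted with a column kit, and libraries were made from 1 ng of total RNA with the QIAseq miRNA kit, which ligates an adaptor to each end of a microRNA. The deposited table holds raw counts, 1 column per library and 1 row per mature microRNA, with no normalization by the authors. Its unit was taken from the values, which are whole numbers with different column totals. Per the submitters' processing notes, cutadapt 1.18 was used, and the genome build was mm10. The aligner, the counting tool and the microRNA annotation are not given in the sources used here, nor is whether reads or unique molecular identifiers were counted. If reads were counted, amplification copies are among them, so counting intervals and floors cover counting error only.

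The groups follow the genotype in the labels, with 6 Ocn-Cre and 10 Prx1-Cre libraries. The design text gives equal numbers of male and female mice in each group, but sex is not given per library, so it did not enter a model. No sequencing batch or date is given in the sources used here. Of 60 pairs of libraries within a group, the least different had a chi-square of 5.04 per degree of freedom, so no library was a repeat of another of its own group within sampling noise.

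The table holds 1915 entries, of which 973 had at least 1 count and 942 were at 0 in every library. After the filterByExpr filter by group, 234 entries were tested, and they held at least 99.7% of the counts of each library. Differential abundance was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM factors, robust fit, group as the only term), with Benjamini-Hochberg adjustment over the entries tested and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM values per library, computed from the deposited counts, use TMM-scaled totals unless stated otherwise. Arm usage was tested with limma 3.58.1 on the log2 ratio of the 5p to the 3p count, with 0.5 added to each, for 44 hairpins with both arms tested.

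Before the data were examined, 18 lists of microRNAs were fixed: mesenchymal and stromal, reported to promote osteoblast differentiation, reported to restrain it, osteoclast, chondrocyte, erythroid, myeloid and pan-leukocyte, lymphoid, endothelial, skeletal and cardiac muscle, adipocyte, liver, epithelial, neural, the let-7 family, the Mir17 cluster with its paralogs, the Dlk1-Dio3 imprinted locus, and entries that overlap rRNA, tRNA or snoRNA. Some microRNAs stand in more than 1 list. The 16 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Summed CPM per list used library totals and a pseudocount of 1 CPM. Values per library were compared by exact permutation tests over all 8008 splits of the 16 libraries into groups of 6 and 10, 2-sided unless stated otherwise, with scipy 1.17.1. Distances between libraries were 1 minus the Spearman correlation of log2 CPM. For counts of detected microRNAs, every library was thinned to 225273 counts, the total of the shallowest.

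The microRNAs named in the text were chosen by a rule fixed before the data were examined: the 10 with the smallest adjusted p in each direction, the 10 most abundant in each group, up to 4 members of each list with the smallest p together with the most abundant member of each list of another cell type, and the hairpins past the threshold for arm usage. A name outside the rule is marked where it appears. Hairpin positions are from the GENCODE annotation of the mm10 assembly, in which 1897 of the 1915 entries matched a hairpin gene by name, and a mature microRNA with several hairpins cannot be assigned to any single one.

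The alternatives were DESeq2 1.42.0, limma voom with quality weights, other scalings, other low-count filters, thinned counts, a block on the replicate number, 6 Prx1 libraries in place of 10, abundant or overlapping entries removed, a fit that was not robust, and each library left out in turn. After seeing the data, 3 alternatives were added: removal of each library's GC trend, log10 of the library total as a covariate, and removal of one of a pair of entries with near-identical counts. The test was tried on 20 simulated data sets drawn from the means, dispersions and library sizes of the 973 entries, with 200 entries changed in each. For Ocn over Prx1, with 233 entries tested on average, 45.8% of the tested entries changed 1.5-fold were recovered, 90.4% of those changed 2-fold and 100% of those changed 4-fold. False calls made up 4.92% of the calls. The simulated entries were drawn independently, while real entries can vary together (estimated correlation of 0.53 in the let-7 list). This share may therefore not hold for these libraries.

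Library totals ran from 225273 to 1536421 counts. A count of 0 allows up to 3 counts, or 13.3 CPM in the shallowest and 1.95 CPM in the deepest library, and 100 counts carry a counting error of 10%.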

Results

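MicroRNAs were counted in EVs of bone marrow plasma from 6-month-old C57BL/6N mice. The CAGS-Snorkel reporter was combined with Ocn-Cre, driven by the osteocalcin promoter of mature osteoblasts and osteocytes, in 6 mice (3 male and 3 female), or with Prx1-Cre, active in the early limb mesenchyme and its descendants, in 10 mice (5 male and 5 female). These groups are called Ocn and Prx1. The libraries held 582660 to 1536421 counts in Ocn and 225273 to 813770 counts in Prx1. Depth thus differed with the group: log10 totals were 5.94 ± 0.17 (SD, n = 6) in Ocn and 5.58 ± 0.16 (SD, n = 10) in Prx1 (exact permutation test, p = 0.00112). Libraries from mice without Cre or from unselected plasma were not analysed here, so no background level stands beside these values.

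miR-16-5p and let-7f-5p had the highest mean CPM in both groups. miR-16-5p reached 135129 ± 17904 CPM (SD, n = 6) in Ocn and 136150 ± 16289 CPM (SD, n = 10) in Prx1, and let-7f-5p reached 128777 ± 24969 CPM in Ocn and 127817 ± 12886 CPM in Prx1. Further abundant entries included miR-142a-3p, a microRNA of blood cells, with 41789 ± 14820 CPM in Ocn and 39280 ± 5153 CPM in Prx1. The muscle microRNA miR-1a-3p had 47443 ± 7356 CPM in Ocn and 37581 ± 10969 CPM in Prx1, and its log2 fold change of 0.34 (SE 0.17) missed the threshold (edgeR adjusted p = 0.187). The 10 most abundant microRNAs of a library held 67.2% ± 2.9 of its counts in Ocn (SD, n = 6) and 66.4% ± 1.3 in Prx1 (SD, n = 10; exact permutation test, p = 0.455). At equal depth, 417.5 ± 11.1 microRNAs were detected in Ocn and 415.8 ± 9.3 in Prx1 (exact permutation test, p = 0.758). Without thinning the means were 567.8 and 469.2, with more in the deeper Ocn libraries (exact permutation p = 0.000874).

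The first comparison asked which microRNAs differed between EVs captured with the osteoblast driver and those captured with the limb mesenchyme driver. In Ocn, miR-181a-5p was 1.52-fold higher (3042 ± 354 against 1995 ± 267 CPM), miR-27a-3p was 1.59-fold higher (685 ± 95 against 432 ± 91 CPM) and miR-19b-3p was 1.57-fold higher (645 ± 185 against 409 ± 108 CPM; SD, n = 6 and 10 throughout). In Prx1, miR-150-5p, a microRNA of mature lymphocytes, was 2.07-fold higher (835 ± 205 CPM in Ocn against 1726 ± 534 in Prx1). miR-574-3p was 1.96-fold higher in Prx1 (72.4 ± 16.6 against 142 ± 17 CPM), and the abundant miR-29a-3p was 1.69-fold higher there (12387 ± 1327 against 20911 ± 5916 CPM). miR-30d-5p followed the same direction at 1.49-fold (7340 ± 521 against 10965 ± 2145 CPM).

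In all, 32 of 234 tested microRNAs passed the threshold, 14 higher and 18 lower in Ocn, and 62 had an unadjusted p under 0.05. The size of the log2 fold change of the 32 ran from 0.36 to 2.71, with a median of 0.67. The libraries of the groups did not overlap for 7 of them, where chance gives 0.025% of microRNAs. The log2 fold changes, with edgeR adjusted p, were 0.61 (SE 0.11, adjusted p = 0.00125) for miR-181a-5p, 0.66 (SE 0.14, adjusted p = 0.00299) for miR-27a-3p, -0.97 (SE 0.16, adjusted p = 0.000563) for miR-574-3p and -1.05 (SE 0.20, adjusted p = 0.00125) for miR-150-5p. In each of these 4, all 6 Ocn libraries lay on the same side of the Prx1 mean. With the log10 library total as a covariate, an alternative added after seeing the data, 0 calls were left with edgeR and 40 had an unadjusted p under 0.05, as the median SE of the 32 rose from 0.167 to 0.256 while their log2 fold changes kept their sign and a median of 0.951 of their size. Upper quartile scaling, which moved the median of all log2 fold changes by 0.124, gave 26 higher and 11 lower in place of 14 and 18. The 14 higher calls became 24 with voom, 8 after thinning, 9 without Prx1 1, 8 without Prx1 2 and 9 without Prx1 3.

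**Figure D1:**
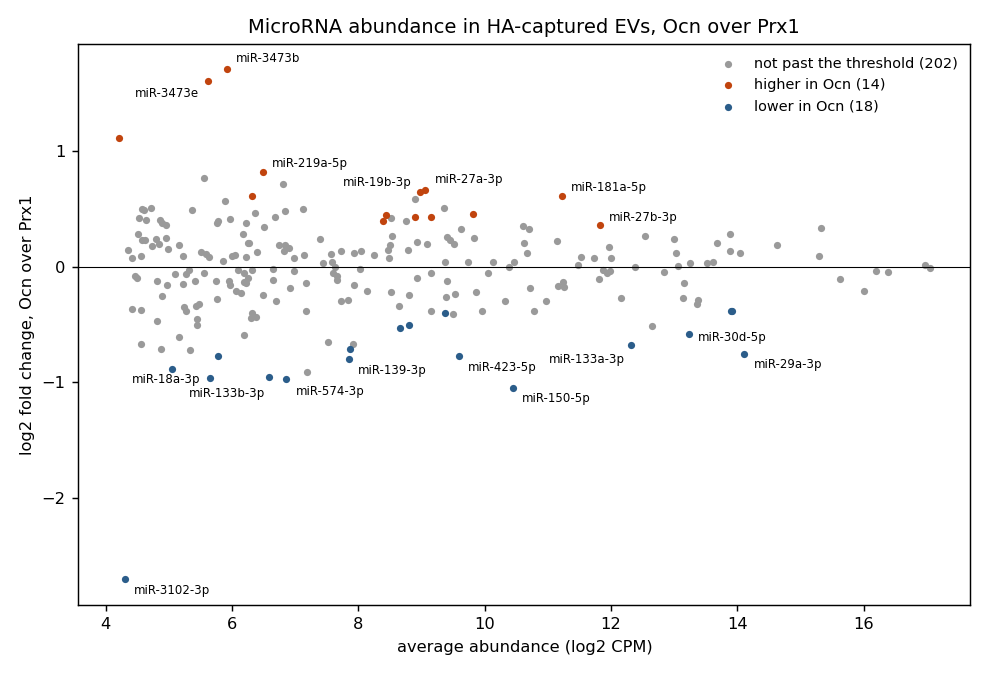
Log2 fold change of Ocn over Prx1 against average abundance in log2 CPM for the 234 tested microRNAs, each point a microRNA from 6 Ocn and 10 Prx1 libraries. The 14 orange points are past the threshold and higher in Ocn, the 18 blue points are past it and lower in Ocn, and most of the 32 lie between -1 and 1.

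Only 5 of the 32 had a log2 fold change of at least 1 in size. The near-identical miR-3473b (1.71, SE 0.39, edgeR adjusted p = 0.00655) and miR-3473e (1.61, SE 0.41, edgeR adjusted p = 0.0106) were higher in Ocn but low in abundance, at 94.3 ± 82.6 against 28.5 ± 12.97 CPM and 74.3 ± 65.1 against 24.0 ± 13.3 CPM. Reads of these 2 entries may be shared, as also between miR-27a and miR-27b, miR-133a and miR-133b, and miR-181a and miR-181c, and Ocn 6 lay far above the other Ocn libraries in both. Without Ocn 6 their log2 fold changes were 1.20 and 1.11 (edgeR adjusted p = 0.0140 and 0.0295). miR-3102-3p was lower in Ocn (-2.70, SE 0.54, edgeR adjusted p = 0.00249), with 4.16 ± 3.57 CPM in Ocn and 29.1 ± 19.6 CPM in Prx1, close to the limit of detection. The others were miR-150-5p and miR-5128 (1.11, SE 0.36, edgeR adjusted p = 0.0451), the latter outside the naming rule and named after its value was seen. miR-5128 was lost in each of the 6 fits with a library left out that tested it. Among the Ocn libraries miR-5128 was highest in Ocn 6 (38.6 CPM) and lowest in Ocn 3 (6.32 CPM). The miR-3473 entries were highest and lowest in the same libraries, so these entries may not be independent.

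The remaining named microRNAs higher in Ocn were miR-219a-5p (0.82, SE 0.20), miR-181c-5p (0.61, SE 0.17), miR-22-3p (0.45, SE 0.13), miR-872-5p (0.43, SE 0.11) and miR-27b-3p (0.36, SE 0.11), with edgeR adjusted p between 0.00981 and 0.0220. Those lower in Ocn were miR-18a-3p (-0.96, SE 0.18), miR-133b-3p (-0.96, SE 0.24), miR-139-3p (-0.80, SE 0.19), miR-423-5p (-0.77, SE 0.17) and miR-133a-3p (-0.68, SE 0.16), with edgeR adjusted p between 0.00125 and 0.0101. miR-27b-3p missed the threshold with any of 6 libraries left out (highest adjusted p = 0.0817), and miR-22-3p without Prx1 2 or Prx1 3 (highest adjusted p = 0.0540). Without a low-count filter miR-872-5p, miR-22-3p, miR-181c-5p and miR-27b-3p missed the threshold. After thinning miR-18a-3p (edgeR adjusted p = 0.0529), miR-872-5p, miR-22-3p and miR-27b-3p did so, miR-872-5p did so also with the GC trend removed, and miR-3473e did so with 6 Prx1 libraries in place of 10 (edgeR adjusted p = 0.0593).

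The hairpins of these microRNAs lie on several chromosomes of mm10. Mir574 is in an intron of Fam114a1 (chromosome 5, 64970318 to 64970395, plus strand), Mir150 lies outside annotated genes of its strand (chromosome 7, 45121757 to 45121821, plus strand), and Mir27a likewise (chromosome 8, 84208672 to 84208758, plus strand). miR-181a-5p comes from Mir181a-1 (chromosome 1, 137966455 to 137966541), in an intron of the noncoding Gm4258, and from Mir181a-2 (chromosome 2, 38852735 to 38852810). Mir29a (chromosome 6, 31062660 to 31062747, minus strand) has no host gene on its strand, and Mir30d (chromosome 15, 68341208 to 68341289, minus strand) lies in an exon of the lincRNA Gm20732. Mir3102 lies in an exon of Arhgef17 (chromosome 7, 100882306 to 100882409, minus strand). Mir18, the source of miR-18a, lies in an exon of Mir17hg (chromosome 14, 115043851 to 115043946, plus strand).

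**Figure D2:**
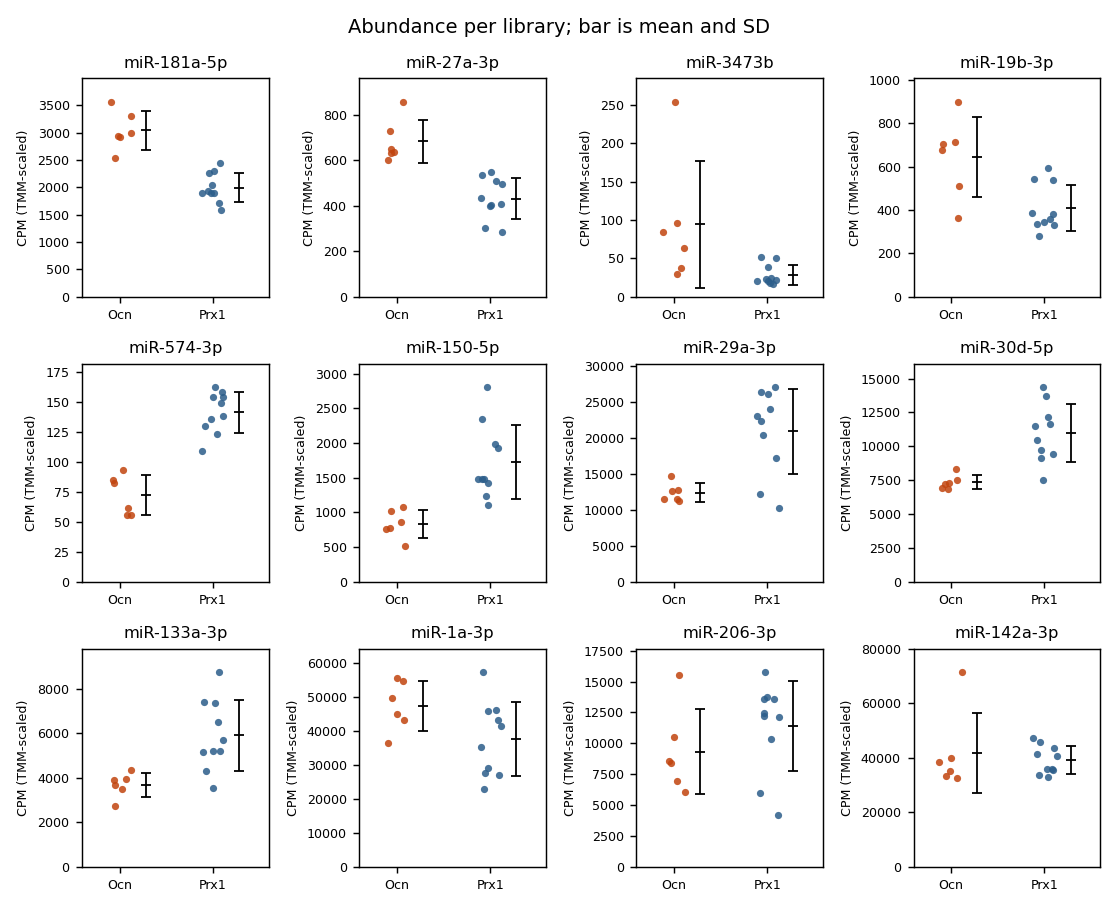
TMM-scaled CPM of 12 microRNAs in each of the 6 Ocn (orange) and 10 Prx1 (blue) libraries, with the mean and SD of each group as a black bar. The Ocn and Prx1 points do not overlap for miR-181a-5p, miR-27a-3p, miR-574-3p and miR-150-5p, while those of miR-1a-3p, miR-206-3p and miR-142a-3p overlap.

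The second question was whether microRNAs known from bone or from other cells of the marrow moved together. Of the 18 tested mesenchymal and stromal microRNAs, 3 were higher in Ocn and 0 lower, namely miR-22-3p, miR-99a-5p (0.45, SE 0.14) and miR-199a-5p (0.43, SE 0.13). Adjusted over the list alone, 3 were higher and 1 was lower, miR-10b-5p (-0.41, SE 0.14). Of 12 microRNAs reported to promote osteoblast differentiation, 2 were higher in Ocn (miR-181a-5p and miR-218-5p, 0.39, SE 0.12) and 1 was lower (miR-29a-3p), with the same counts adjusted over the list alone. The median log2 fold change of that list was 0.17 while its summed CPM, which includes the abundant miR-29a-3p, had a log2 difference of -0.10 (exact permutation p = 0.211, adjusted p = 0.492). Of 18 reported to restrain osteoblast differentiation, 1 was higher (miR-27a-3p) and 2 were lower (miR-30d-5p and miR-133a-3p), with the same counts adjusted over the list alone. The calls of miR-99a-5p, miR-218-5p and miR-199a-5p were lost with any of 8, 6 and 7 libraries left out, respectively. Those of miR-218-5p and miR-199a-5p were lost also without a low-count filter, with the replicate block and after thinning. That of miR-199a-5p was further lost with 6 Prx1 libraries in place of 10 and with the 5 most abundant microRNAs removed.

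Among microRNAs of blood cells, 2 of 5 erythroid entries were lower in Ocn, miR-486a-5p (-0.38, SE 0.13) and miR-486b-5p (-0.38, SE 0.13), whose counts differed by at most 0.016 on the log2 scale, so that their reads may be shared and they are not independent, although each is counted here. Their edgeR adjusted p of 0.0451 and 0.0457 was lost with any of 7 libraries left out and with several other settings, and without Ocn 5 their log2 fold changes were -0.24 and -0.24. The other erythroid members gave 0.58 (SE 0.20) for miR-144-3p, 0.22 (SE 0.18) for miR-451a and 0.17 (SE 0.17) for miR-144-5p, the last outside the naming rule. Adjusted over the list alone, 1 erythroid entry was higher and 2 were lower. The median of this list was 0.17 and its mean 0.04, while its camera direction was down. Of 5 lymphoid microRNAs, 1 was higher (miR-181a-5p) and 1 lower (miR-150-5p), with the same counts adjusted over the list alone. None of 6 myeloid and pan-leukocyte, 8 osteoclast or 2 endothelial microRNAs passed with edgeR, over all tested or adjusted over the list alone, and miR-223-3p had a log2 fold change of -0.27 (SE 0.14).

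Of 4 muscle microRNAs, 2 were lower in Ocn, miR-133a-3p (3689 ± 535 against 5911 ± 1588 CPM) and miR-133b-3p (59.0 ± 15.7 against 116 ± 43 CPM), with the same count adjusted over the list alone. miR-206-3p had a log2 fold change of -0.29 (SE 0.24). The median of the muscle list was -0.48, whereas its summed CPM, mostly miR-1a-3p, had a log2 difference of 0.19 (exact permutation p = 0.219, adjusted p = 0.492). Of 3 neural microRNAs, 1 was higher (miR-219a-5p), with the same count adjusted over the list alone. Of 4 chondrocyte microRNAs 0 passed over all tested, and adjusted over the list alone 1 was higher (miR-140-5p, 0.50, SE 0.21) and 1 lower (miR-140-3p, -0.51, SE 0.19), the arms of a single hairpin. With edgeR, 0 of 5 adipocyte, 2 liver, 3 epithelial, 9 let-7, 7 Dlk1-Dio3 and 3 RNA-overlap microRNAs passed, also adjusted over the list alone.

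Of the 12 tested members of the Mir17 cluster and its paralogs, 1 passed, miR-19b-3p, also adjusted over the list alone. The list holds 1 arm of each hairpin. Among arms left out, miR-18a-3p (-0.96), miR-25-5p (-0.67), miR-106b-3p (-0.30) and miR-93-3p (-0.21) were lower in Ocn, and miR-17-3p (0.13) was higher. Of these only miR-18a-3p passed, and the others are outside the naming rule. The values of the list therefore hold for the arms it names, not for the hairpins as a whole. The summed CPM of the list had a log2 difference of 0.03 (exact permutation adjusted p = 0.856). The list had a median log2 fold change of 0.30, with 11 of 12 members above 0 under TMM scaling. Its camera adjusted p of 0.211 was the smallest of the lists (adjusted p = 0.320 with an estimated correlation). fry, which asks whether the members move one way and not whether they differ from other microRNAs, gave an adjusted p of 0.00320. No list passed camera. The adjusted p was 0.502 for the mesenchymal list, 0.851 for the list reported to promote osteoblast differentiation, 0.587 for the muscle and neural lists and 0.871 for the other 11. The endothelial and liver lists had too few tested members for camera. fry's test for change in either direction passed for 3 lists, with adjusted p of 0.000777 for the mesenchymal list, 2.61e-05 for the list reported to promote and 0.000180 for that reported to restrain osteoblast differentiation. It likewise does not compare members with other microRNAs, and these lists already hold called members, so it does not set them apart. The same fry test gave an adjusted p of 0.802 for the muscle list, of which 2 of 4 passed with edgeR. Summed CPM differed for 0 of 18 lists by exact permutation tests. The smallest adjusted p was 0.166 (unadjusted 0.00924), for the list reported to restrain osteoblast differentiation, with 52887 ± 4678 CPM in Ocn and 58990 ± 3467 CPM in Prx1. With TMM scaling the log2 difference of that list was -0.193 (exact permutation p = 0.00287, adjusted p = 0.0517), just short of the threshold.

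The third question was whether the arms of a hairpin moved together. The 5p to 3p ratio was higher in Ocn for 3 of 44 hairpins, by 1.47 on the log2 scale for miR-18a (SE 0.28, limma adjusted p = 0.00112), 1.10 for miR-574 (SE 0.22, limma adjusted p = 0.00112) and 1.39 for miR-133a (SE 0.34, limma adjusted p = 0.00699). A further 5 were among the 8 hairpins with an unadjusted p under 0.05. In each of the 3 the 3p arm was called lower in Ocn, while the 5p arm, at 0.50 for miR-18a-5p, 0.12 for miR-574-5p and 0.77 for miR-133a-5p, missed the threshold. Across the 44 hairpins, which are not independent replicates, the log2 fold changes of the arms had a Spearman rho of -0.0007, and 19 hairpins had arms of opposite sign. With at least 50 counts over both arms required in every library, 31 hairpins were tested and 1 passed, miR-133a, as the other 2 were not tested. Nearly all of that sum for miR-133a was its 3p arm. miR-133a-5p ran from 8.78 CPM in Prx1 4, the shallowest library, to 82.4 CPM in Ocn 1. Its ratio therefore rests on few 5p counts in some libraries. At least as many as 3 hairpins passed in 5 of 100 splits of the libraries, the real one included, so chance cannot be excluded.

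On average, libraries lay closer to their own group than to the other, in a comparison not made at equal depth. The Ocn libraries were deeper, so depth may add to both the separation and the spread given here. The mean distance was 0.0380 between groups, 0.0253 within Ocn and 0.0334 within Prx1, and the excess of 0.0067 between over within groups had a 1-sided exact permutation p of 0.0020. All 6 Ocn libraries were on average nearer to their own group, while 3 of 10 Prx1 libraries (Prx1 6, Prx1 7 and Prx1 8) were nearer to Ocn. The spread within groups did not differ past the threshold (difference of -0.0080, exact permutation p = 0.237). With Euclidean distance it did, with 7.75 within Ocn and 9.95 within Prx1 (exact permutation p = 0.0482). With a filter of at least 10 CPM in at least 6 libraries, the mean distance was 0.0295 within Ocn, 0.0449 within Prx1 and 0.0450 between groups, the spread differed (exact permutation p = 0.0356), and the 1-sided exact permutation p for the separation was 0.0481.

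Liver microRNAs were compared library by library, as miR-122-5p, outside the naming rule, was below the filter. It had 555 counts in Prx1 5, or 1644 CPM of the library total, and 0 to 19 counts in each other library.

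**Figure D3:**
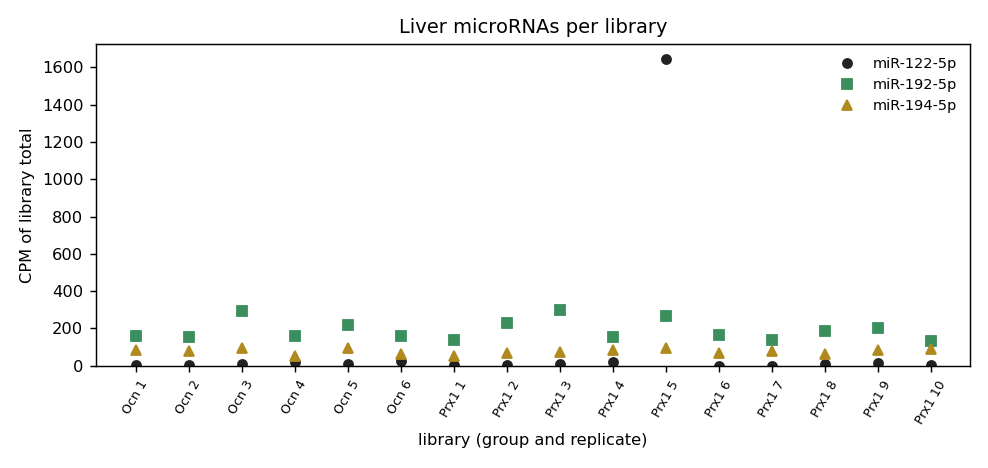
CPM of the library total for miR-122-5p, miR-192-5p and miR-194-5p in each of the 16 libraries, 1 point per library and microRNA. miR-122-5p was 1644 CPM in Prx1 5 and at most 23.5 CPM in the other 15 libraries.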

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

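Of the tests of explanations here, that for carry-over of miR-122-5p between libraries was chosen only after the result was seen. That for liver RNA names Prx1 5, so it was set with the miR-122-5p value of that library known. In 216 groups of libraries, each holding 1 genotype's values of a named or called microRNA, a summed list, the total, the detected microRNAs or the share of the 10 most abundant, 21 held a library far from the rest, where chance gives about 1 in 20, or 10.8.

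The widest gap was in liver microRNAs. Their summed CPM was 2005 in Prx1 5 and 197 to 382 in the other Prx1 libraries. It came from miR-122-5p (mmu-miR-122-5p in the table, outside the naming rule), the main liver microRNA, whose hairpin lies on chromosome 18 (65248861 to 65248926, mm10). That microRNA had 555 of 337645 counts in Prx1 5, or 1644 CPM of the library total (95% Wilson interval 1513 to 1786), and 0 to 23.5 CPM in the other 15 libraries. It was not among the tested entries. Carry-over from another of these 16 libraries would need a source with more miR-122-5p, and the highest other value was 23.51 CPM. That Prx1 5 was the highest was known beforehand, and a source outside these libraries stays open. Liver RNA in that library is a candidate explanation that stays open: miR-192-5p and miR-194-5p, also abundant in liver, ranked 3 and 2 from the highest of 16 in Prx1 5, neither the highest nor the lowest. No biological explanation was tested, since the labels say nothing that sets this mouse apart.

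Of the 21, 8 were in Ocn 3. There miR-142a-3p was 71465 CPM against 32484 to 39768 in the other Ocn libraries, miR-199a-5p was 981 CPM against 553 to 656, miR-19a-3p was 152 CPM against 44.6 to 70.6, and miR-181c-5p was 129.5 CPM against 84.8 to 91.9. miR-455-3p was low in Ocn 3, at 20.5 CPM against 64.3 to 80.2. Summed CPM in Ocn 3 was 57116 for the osteoclast list, 102343 for the myeloid and pan-leukocyte list and 482 for the epithelial list. Without Ocn 3 the comparison of the groups gave 35 calls in place of 32, and 28 were shared.

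In Ocn 6, miR-3473b reached 254 CPM against 30.01 to 96.6 in the other Ocn libraries, and miR-3473e reached 199 CPM against 17.4 to 82.4. Without Ocn 6 the log2 fold changes of Ocn over Prx1 were 1.20 in place of 1.71 and 1.11 in place of 1.61, both still past the threshold. In Ocn 5 summed CPM of the library total was 20837 for the endothelial, 10391 for the adipocyte and 894 for the neural list. Ocn 5 also had the highest TMM factor, 1.10. With TMM scaling miR-126a-3p, most of the endothelial sum, was 17105 CPM in Ocn 5 and 17547 CPM in Ocn 6. These flags in Ocn 5 may thus depend on the scaling, and they were not repeated with TMM. miR-18a-3p was 38.2 CPM in Ocn 2, and miR-155-5p was 504 CPM in Ocn 4, each above the other Ocn libraries. Among the Prx1 libraries, miR-23a-3p was high in Prx1 7 (2123 CPM), miR-378a-3p in Prx1 10 (5894 CPM), miR-9-5p in Prx1 8 (41.6 CPM) and miR-6240 in Prx1 6 (120 CPM), while miR-181b-5p was low in Prx1 1 (480 CPM).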

How the results depend on the processing

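The tests added after seeing the data were those with the GC trend removed, with log10 of the library total as a covariate, and with one miR-486 entry left out. The 32 calls became 42 with DESeq2 (31 shared), 48 with voom (32 shared), 31 with RLE factors (30 shared), 37 with upper quartile factors (25 shared), 30 with library totals (29 shared), 27 without a low-count filter (19 shared), 24 after thinning (22 shared), 30 with the GC trend removed (27 shared) and 31 with one miR-486 entry out (31 shared). The calls higher in Ocn, 14 in the report, were 24 with voom, 26 with upper quartile factors and 8 after thinning, and those lower in Ocn were 11 with upper quartile factors; the cause was not tested. With log10 of the total as a covariate, 0 calls were left, 0 higher and 0 lower, because standard errors rose (median 0.167 to 0.256). With each library left out, calls ranged from 24 to 36, those higher in Ocn from 8 to 20 and those lower from 13 to 20. The higher calls fell furthest without Prx1 1 (9), Prx1 2 (8) and Prx1 3 (9). Of the 32, 20 passed with each library left out, and 14 of them also under every other setting that tested them except the depth covariate (15 settings, or 13 for miR-3102-3p). No called value changed sign; of values that passed no test, the difference in detected microRNAs changed from 1.7 to -0.7 with at least 5 counts required, and the summed CPM of the myeloid, lymphoid and Mir17 lists changed sign with TMM scaling.

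Both groups carry replicate numbers 1 to 6, and the sources used here do not say that these pair the libraries. Deviations of the 6 same-numbered pairs correlated between 0.0223 and 0.202, and 3 pairs were over 0.1. Only 1 Ocn library correlated best with its own number, so a link by number was neither shown nor excluded. With the replicate number as a block, 27 calls were made, 23 of them shared, and miR-19b-3p and miR-872-5p were among those lost. The list tests gave 0 lists with camera under every setting run, and 1 with fry, which asks another question. With at least 50 counts over both arms, 1 hairpin passed in place of 3, since 31 were tested. Without thinning the groups differed by 98.6 detected microRNAs (exact permutation p = 0.000874), as depth differs. The spread within Ocn minus that within Prx1 was -2.20 with Euclidean distance (exact permutation p = 0.0482); the cause was not tested. Depth limits low entries most, since a count of 0 allows 13.3 CPM in the shallowest library.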

Other observations

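The tests on runs of C and on muscle RNA were chosen only after the results they concern were seen. The libraries Prx1 6 and Prx1 7 had values of -2.32 and -3.05 on the first principal component (25.0% of variance), where the Ocn libraries had values from -4.80 to -2.07 and the other Prx1 libraries from 0.94 to 6.28.

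The 32 calls between the groups were set against chance, depth and base composition. Of 100 splits of the 16 libraries, the real one included, 1 gave as many calls, and the highest of the others gave 8. This argues against chance, although only 100 of the 8008 splits were drawn. The trend on depth within the 10 Prx1 libraries, scaled to the gap between groups, predicted a median share of 0.02247 of the fold changes (-0.0471 to 0.201 with a Prx1 library left out), which argues against depth as the whole cause, although depth and group overlap so far that no call was left with depth as a covariate. GC was taken from the part of the hairpin that holds the arm, or from the whole hairpin for entries without an arm. Its median was 55.26% for lower calls, 50.91% for higher calls and 47.9% for uncalled entries (Spearman rho with log2 fold change, -0.18). With each library's trend on this GC removed, 27 of the 32 calls stayed past the threshold, with a median of 0.971 of their log2 fold change. These values argue against GC of that part as the whole cause. GC of the mature microRNA was not tested, so its share stays open. A biological difference between the drivers stays open, and so do differences between the groups that the labels do not record.

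A run of CCC stood in the part of the hairpin that holds the arm for 15 of the 18 microRNAs lower in Ocn, 7 of the 14 higher and 73 of 201 others with a sequence (Fisher's exact test of the lower against the others, p = 0.000184). With one of the miR-486 entries left out it stood in 14 of 17 lower calls (Fisher's exact p = 0.000376). Neither test took GC into account, and median GC was 55.26% for lower calls and 47.9% for uncalled entries. They therefore do not separate such runs from GC. A trend on such runs across libraries may be one source. A score per library, the mean deviation of microRNAs with the run minus that of the rest, differed by -0.12 (Ocn minus Prx1) over all tested entries (95% jackknife interval -0.216 to -0.0253, exact permutation p = 0.0187, adjusted p = 0.0442 over 4 tests), which largely restates the enrichment that prompted it. Among microRNAs not past the threshold the difference was -0.0455 (exact permutation p = 0.3565), but leaving out the calls by itself shrinks the score, so this decides nothing and the source stays open. The same score for GGG differed by -0.0561 over all tested entries (exact permutation p = 0.273, adjusted p = 0.357) and by -0.107 among those not past the threshold (exact permutation p = 0.0221, adjusted p = 0.0442). The 95% jackknife interval of the latter, -0.230 to 0.0164, spans both signs, so the interval and the permutation test differ.

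The shift in arm ratio of 3 hairpins was matched or exceeded in 5 of 100 splits, the real one included, with 6 hairpins in the highest of the others, so chance cannot be excluded. With the GC trend removed, 3 of the 3 hairpins stayed past the threshold. This argues against GC of the part of the hairpin that holds each arm as the whole cause. GC of the mature arms was not tested. Of the same splits, 80 gave a list with a camera p as small as the smallest real one of 0.0132 (the smallest of the others was 7.59e-08), so chance cannot be excluded for the lists.

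Less muscle RNA in Ocn was a hypothesis for the lower miR-133a-3p and miR-133b-3p. It would lower miR-1a-3p alike, yet the log2 fold change of miR-1a-3p was 0.34 (SE 0.17), against -0.68 (SE 0.16) and -0.96 (SE 0.24) for the pair, which argues against it as the whole cause. miR-206-3p, at -0.29 (SE 0.24), leaves a part of it open. The log2 ratio of miR-1a-3p to miR-133a-3p was 3.68 ± 0.34 in Ocn (SD, n = 6) and 2.66 ± 0.65 in Prx1 (SD, n = 10), a difference of 1.02 (exact permutation p = 0.004745), but that p largely restates the call of miR-133a-3p, which was picked for being lower.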
